A study of Homo sapiens with 4 samples.

How the data were processed

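Poly(A) RNA of 4 OCI-AML3 cultures was sequenced from libraries made with the NEBNext Ultra II Directional kit, per the labels' protocols. The labels state that each vector was introduced in 2 independent transductions, so the spread between libraries of a group covers separate transductions of 1 cell line. The deposited table holds raw read counts per Ensembl gene, with 1 column per library, as deposited by the authors. The submitters' processing notes name FastQC 0.11.4, STAR 2.5, HTSeq without a version and the genome build hg38. The annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart with certainty, and reads shared by close paralogs may be dropped or split, so values of such genes are uncertain.

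Of 67062 rows, 60402 had a symbol in the reference table of gene names, and rows without one held 0.0723% of the counts. Gene types and coordinates came from GENCODE release 29 on GRCh38, the same assembly as hg38. A count above 0 in any library was found for 29600 genes, and filterByExpr of edgeR (minimum count 10, minimum total 15) left 15918 for testing. Total counts per library ran from 29819572 to 38358442, and levels are given as CPM, counts relative to the TMM-scaled library total. Counting precision at this depth is high for abundant genes, and the biological coefficient of variation was 2.95%. Replicates were compared before they were averaged. The chi-square per gene was 1.81 between the PIG-EMPTY libraries and 4.67 between the PIG-LONA libraries, above the value of 1 that counting noise alone would give, so all 4 libraries were kept as separate samples.

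Differences were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood functions glmQLFit (legacy form off) and glmQLFTest on a design with an intercept and the group, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1, two-sided, at a preset correlation of 0.01. Adjustment ran over the 33 of 35 lists that had at least 5 tested members. At the preset value camera takes its degrees of freedom from the number of genes and treats list members as nearly independent. Spread between libraries that moves the members of a list together therefore hardly enters that p. Of the 15 lists called, 0 held in camera with a correlation estimated per list (5 lists had an unadjusted p under 0.05 there, the smallest 0.00556), while fry, which asks whether the members of a list move on balance in 1 direction, called 7. The lists were written from textbook knowledge before the data were examined, as were the tests and the rule for named genes. They covered myeloid lineages and regulators, genes tied to mutant NPM1, the cell cycle, stress and metabolism, RNA quality and markers of other cell types, and some genes stand in more than 1 list.

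Genes were named by this rule. Among genes with adjusted p under 0.05, non-overlapping groups and a mean raw count of at least 50 in the higher group, the 8 with the largest rise, the 8 with the largest fall and the 5 per direction with the smallest p were taken. Each list added up to 4 members with the smallest p among those past the threshold, or 2 members as values only where it had none. NPM1, HOXA9, MEIS1, CEBPA, SPI1, CD14, ITGAM, CD34, KIT, MYC and MPO were named in any case. The rule gave 125 tested genes. Not every one of them is reported here. Of these, 110 passed the test, and 50 of the 110 stayed past it under every other setting, of up to 16, that gave them an adjusted p. AKR1C1, ERV3-1, EGR1 and GFI1 in the report and the genes of the closing observations were named after their values were seen.

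The test was checked on simulated counts for this comparison, drawn from the real means, library sizes and dispersions, with 200 genes changed by known folds and 15677 genes tested. It recovered 42.9% of genes changed 1.2-fold, 65.3% of those changed 1.5-fold, 79.6% of those changed 2-fold and 95.8% of those changed 4-fold. Another 10 calls (6.76% of all calls) were false, and 0 lists were called where no list effect was simulated. Each gene was drawn independently, so the simulated lists held no correlation between members. The 0 therefore does not bear on lists with correlated members, such as the ribosomal protein genes, estimated at 0.878. A simulated shift of 0.2 (log2) of chromosome 7 was recovered as a median of 0.195.

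The alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling or library totals in the same test, the DESeq2 Wald test, limma-voom, the legacy form of the edgeR test, no filter beyond 1 count, a filter of CPM of at least 1 in at least 2 libraries, the replicate number as a block, each library left out in turn, adjusted p under 0.01, at least 2-fold, an estimated correlation and fry. After the data were seen, 3 were added. They leave out chromosome 6 genes, remove a trend on GC content and transcript length from each library, or remove the median deviation of chromosome 6 genes from each library. The GC and length values covered 99.1% of the tested genes. Genes of chromosome Y were left out of the search for genes counted in a single library. With groups of 2 libraries, no test for outlying libraries was made. A fit without 1 library takes its residual spread from the pair of the other group alone. A call lost there need not depend on the library left out.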

Results

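RNA of OCI-AML3 cells, an established human acute myeloid leukaemia line that carries the cytoplasmic NPM1 mutation, was sequenced after retroviral transduction. Cells received a pMSCV-PIG vector that drives the long noncoding RNA LONA (PIG-LONA) or the same vector without an insert (PIG-EMPTY), and GFP-positive cells were sorted before RNA extraction. Each vector was introduced in 2 independent transductions, which gave 2 libraries per group and 4 in total. Total counts were 29819572 and 32350832 in the PIG-EMPTY libraries and 30181550 and 38358442 in the PIG-LONA libraries. Mitochondrially encoded transcripts took 6.32% to 7.10% of the counts and cytosolic ribosomal protein genes 5.52% to 5.84%, with no separation of the groups in either share. The level of LONA itself is not reported here, because no row was matched to it by name. The labels therefore stand without a check from the expressed transcript.

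The comparison of PIG-LONA with PIG-EMPTY asks what overexpression of LONA does to the transcriptome of these cells, whose delayed myeloid differentiation is the subject named by the series. PIG-LONA cells had lower levels of monocyte and macrophage markers, late neutrophil genes and adhesion and matrix genes, and slightly higher levels of DNA replication genes. These list-level differences were called by camera at a preset correlation and not with an estimated one (adjusted p = 0.184, 0.250, 0.221 and 0.308 in that order). Fry called the falling lists (adjusted p = 0.0246, 0.0484 and 0.0403) but not the G1 and S phase list that holds the replication genes (adjusted p = 0.0800). The estimated form rests on 2 residual degrees of freedom, so hardly any list could pass it and its missing calls decide little. The estimated correlations were 0.0133 for monocyte, 0.101 for late neutrophil, 0.0315 for adhesion and 0.150 for G1 and S phase genes, against the preset 0.01. Where the estimate lay well above the preset value, as for late neutrophil and G1 and S phase genes, the preset p is likely too small. Of 15918 genes tested, 1025 differed, 467 higher and 558 lower in PIG-LONA (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most differences were small, with a median absolute log2 fold change of 0.27 (1.21-fold) among the 1025 genes. At least 1.5-fold changes were mostly decreases, 149 against 22 increases, and at least 2-fold changes were decreases in 65 genes and increases in 3. In all 1025 genes both PIG-LONA libraries lay on the same side of both PIG-EMPTY libraries, an arrangement that chance gives for 33.3% of genes and that held for 48.0% of all tested genes. Of the 467 higher genes, 226 lay on chromosome 6, whose genes as a whole were higher in PIG-LONA. With the median shift of chromosome 6 removed from each library, 232 genes were higher and 531 lower. The count of 1025 was 473 with DESeq2, 334 without a filter on low counts, 660 without chromosome 6 genes, 644 without PIG-EMPTY replicate 1, 466 without PIG-EMPTY replicate 2 and 2331 without PIG-LONA replicate 1.

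Among the genes that fell was THBS1. This gene, which encodes the matrix glycoprotein thrombospondin 1 (chromosome 15, 39581079 to 39599466, GRCh38), fell from 13.2 ± 1.21 to 2.65 ± 0.01 CPM (mean ± SD, n = 2 per group), a log2 fold change of -2.32 ± 0.13 (SE; edgeR adjusted p = 3.03e-10). IGFBP5, a secreted binding protein of insulin-like growth factors (chromosome 2, 216672105 to 216695525), fell from 107 ± 2.72 to 51.7 ± 0.59 CPM, with the smallest p of all genes (log2 fold change -1.05 ± 0.04, edgeR adjusted p = 6.72e-12). JAML, a junctional adhesion molecule of leukocytes, had a log2 fold change of -2.15 ± 0.22. The lipid transporter gene ABCA6 was at -2.08 ± 0.25, the adhesion gene CADM1 at -1.47 ± 0.22, MPZL3 at -1.51 ± 0.21, MGAM2 at -1.56 ± 0.27 and the noncoding host gene MIR124-1HG at -1.48 ± 0.18. Among called genes with a mean of at least 50 counts in PIG-EMPTY, UGT3A2 had the lowest log2 fold change, -3.74 ± 0.69, but its counts were 102 and 22 in the PIG-EMPTY libraries against 5 and 5 in the PIG-LONA libraries. Its call was lost without the low-count filter.

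**Figure D1:**
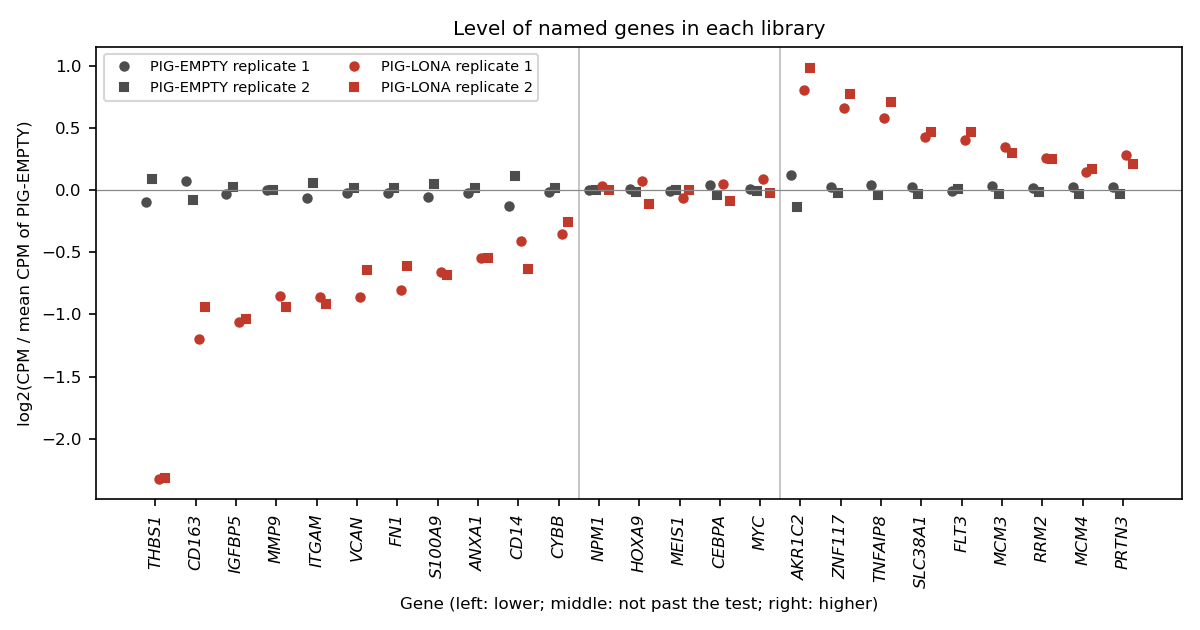
Each point is 1 library, and its height is the log2 ratio of that library's CPM (counts relative to the TMM-scaled library total) to the mean CPM of the PIG-EMPTY libraries for the gene on the horizontal axis; grey symbols are PIG-EMPTY and red symbols PIG-LONA. Both PIG-LONA libraries lie below both PIG-EMPTY libraries for the 11 genes on the left, with THBS1 lowest at a log2 fold change of -2.32, and above them for the 9 genes on the right, with AKR1C2 highest at 0.91.

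Among the genes that rose was AKR1C2. This aldo-keto reductase gene (chromosome 10, 4987400 to 5018031) rose from 44.5 ± 5.71 to 83.0 ± 7.35 CPM (log2 fold change 0.91 ± 0.07, edgeR adjusted p = 3.89e-08). Its close paralog AKR1C1 was at 0.61 ± 0.07, and reads that fit both copies leave their split uncertain. ZNF117, a zinc finger gene that overlaps ERV3-1 on chromosome 7, rose by 0.72 ± 0.05, and since the overlapping gene was at 0.67 ± 0.08 the counts of this pair cannot be assigned with certainty. Further increases were seen for TNFAIP8 (0.65 ± 0.06), the kinase gene HUNK (0.73 ± 0.08), the glutamine transporter gene SLC38A1 (0.45 ± 0.04), the secreted glycoprotein gene STC2 (0.74 ± 0.11) and ADAMTS10 (0.78 ± 0.15). PM20D2, on chromosome 6, rose by 0.58 ± 0.06. KRT17, SLC9C2, CNTF and EGFL8, the last also on chromosome 6, had log2 fold changes between 0.78 and 0.94 too. The calls of these 4 genes were lost without the low-count filter and without PIG-LONA replicate 2, and those of SLC9C2, CNTF and EGFL8 also without PIG-EMPTY replicate 2.

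Monocyte and macrophage markers fell as a group in PIG-LONA. Of 44 measured members, 25 fell, 0 rose and 19 did not pass the test, and 31 fell when p was adjusted over the list alone. The haemoglobin scavenger receptor gene CD163 fell from 25.2 ± 1.79 to 12 ± 1.5 CPM (log2 fold change -1.05 ± 0.08, edgeR adjusted p = 9.11e-08), and ITGAM, which encodes the integrin subunit CD11b, fell from 9.59 ± 0.55 to 5.18 ± 0.15 CPM (-0.89 ± 0.11, edgeR adjusted p = 4.01e-05). VCAN, a proteoglycan gene of monocytes, was at -0.74 ± 0.05 and the calgranulin gene S100A9 at -0.67 ± 0.05. CD14, the lipopolysaccharide co-receptor, fell from 12.6 ± 1.48 to 8.80 ± 0.97 CPM (-0.53 ± 0.10, edgeR adjusted p = 0.00319). The median of the list was a log2 fold change of -0.44. The list was lower against other genes in camera with the preset correlation (adjusted p = 9.28e-43), whereas camera gave an adjusted p = 0.184 with an estimated correlation. The preset form treats members as nearly independent, so the size of its p does not measure how well the cultures of a group repeat. CD14 lost its call without PIG-EMPTY replicate 2 and without the low-count filter, and 15 members fell without that filter.

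Genes of late neutrophil maturation also moved downward. Of 17 measured members, 8 fell, 0 rose and 9 did not pass, with 10 lower and 1 higher when adjusted over the list alone. The gelatinase gene MMP9 (chromosome 20, 46008908 to 46016561) fell from 69.5 ± 0.02 to 37.4 ± 1.6 CPM (log2 fold change -0.90 ± 0.05), the collagenase gene MMP8 was at -0.85 ± 0.15, and CYBB, a subunit of the phagocyte NADPH oxidase, was at -0.30 ± 0.04. CEACAM6, with counts of 47, 21, 6 and 12 in PIG-EMPTY replicates 1 and 2 and PIG-LONA replicates 1 and 2, was called as well, but not without PIG-EMPTY replicate 1 and not without the low-count filter. Camera gave an adjusted p = 5.64e-13, and adjusted p = 0.250 with an estimated correlation. Genes of the early, primary granules went both ways. PRTN3 (0.25 ± 0.04) and AZU1 (0.15 ± 0.04), both granule serine protease family genes, rose and ANXA1 (-0.54 ± 0.04), an annexin gene, fell among 16 measured members (4 higher and 1 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.789) except without PIG-LONA replicate 2, where it was higher (adjusted p = 0.0491). AZU1 lost its call without either PIG-EMPTY library and without the low-count filter. The count of fallen late neutrophil genes was 5 without PIG-EMPTY replicate 1, 4 without PIG-EMPTY replicate 2, 5 with DESeq2 and 3 without the low-count filter.

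Adhesion, integrin and matrix genes fell in 18 of 51 measured cases, with 0 rises and 33 not passing, and 24 fell and 1 rose when adjusted over the list alone. Besides THBS1 and MMP9, the list held fibronectin (FN1), which fell from 78.9 ± 1.47 to 48.5 ± 4.55 CPM (log2 fold change -0.70 ± 0.05, edgeR adjusted p = 6.51e-08), and galectin 1 (LGALS1, -0.44 ± 0.04). In camera the list had an adjusted p = 7.27e-21, and adjusted p = 0.221 with an estimated correlation. Of 10 measured megakaryocyte and platelet genes, 4 fell and 0 rose, and the count was 4 when adjusted over the list alone. They were THBS1, the platelet chemokine gene PPBP, RAB27B (-0.64 ± 0.11) and SPARC (-0.47 ± 0.08). PPBP had counts of 49 and 49 in PIG-EMPTY and 6 and 14 in PIG-LONA. For this list the camera adjusted p was 1.83e-10, and adjusted p = 0.221 with an estimated correlation. RAB27B lost its call without the low-count filter.

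Among 35 measured myeloid transcription factors, 8 fell and 2 rose (9 and 4 adjusted over the list alone). PPARG (-0.46 ± 0.08), the AP-1 gene FOS (-0.38 ± 0.06) and CEBPD (-0.25 ± 0.05) fell, and SPI1, which encodes the myeloid regulator PU.1, was lower by a small margin (226 ± 3.14 against 206 ± 6.03 CPM, log2 fold change -0.13 ± 0.04, edgeR adjusted p = 0.0346). EGR1 (0.19 ± 0.05) and GFI1 (0.13 ± 0.04), named here after their values were seen as the 2 that rose, went the other way. CEBPA, a driver of granulocytic differentiation, was at -0.02 ± 0.04 and did not pass (edgeR adjusted p = 0.878). The camera adjusted p of the list was 0.018, and adjusted p = 0.512 with an estimated correlation. The list was not called without PIG-EMPTY replicate 1 or without PIG-LONA replicate 2, and 5 members fell without PIG-EMPTY replicate 1, 5 with DESeq2 and 3 without the low-count filter. SPI1, EGR1 and GFI1 lost their calls without either PIG-EMPTY library, with DESeq2 and without the low-count filter, and SPI1 also without chromosome 6 genes. CEBPD lost its call without PIG-EMPTY replicate 1 and without the filter.

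Lysosome genes fell in 8 of 37 measured cases with 0 rises (13 lower and 1 higher adjusted over the list alone). These included the cathepsin genes CTSH (-0.45 ± 0.05), CTSZ (-0.22 ± 0.04) and CTSS (-0.27 ± 0.05), and ATP6V0D2, a proton pump subunit with counts of 44 and 35 in PIG-EMPTY and 4 and 10 in PIG-LONA. By camera the adjusted p was 4.82e-06, and adjusted p = 0.240 with an estimated correlation. MHC class II and its processing had 2 falls among 9 measured members (3 adjusted over the list alone), and both were proteases, CTSS and CTSL (-0.30 ± 0.06), not class II molecules. Camera gave an adjusted p = 0.0107 for that list, and adjusted p = 0.308 with an estimated correlation. Of 13 retinoid and vitamin D response genes, 2 fell (3 adjusted over the list alone), the thrombomodulin gene THBD (-0.34 ± 0.05) and ASB2 (-0.73 ± 0.17), with a camera adjusted p = 0.00765, and adjusted p = 0.308 with an estimated correlation. Of 7 measured lymphoid genes, 2 fell (3 adjusted over the list alone), the granzyme gene GZMA (-0.52 ± 0.08) and the receptor gene IL7R (-0.25 ± 0.05), with a camera adjusted p = 0.0143, and adjusted p = 0.308 with an estimated correlation. The lysosome count was 4 without PIG-EMPTY replicate 2, 13 without PIG-LONA replicate 1, 5 with DESeq2 and 4 without the low-count filter, and the count of retinoid and vitamin D genes was 1 without PIG-EMPTY replicate 2, with DESeq2 or without the filter. The MHC class II list was not called without PIG-EMPTY replicate 1, nor the lymphoid list without PIG-EMPTY replicate 2 or without the filter. Without the filter each of these lists had 1 fall.

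NF-kB and inflammatory genes had 6 falls and 2 rises among 31 measured members (8 and 3 adjusted over the list alone). The chemokine genes CCL2 (-0.69 ± 0.10) and CCL5 (-0.18 ± 0.05) fell, while TNFAIP8 and SOD2 (0.22 ± 0.05, on chromosome 6, whose median was 0.17) rose. The camera adjusted p was 0.0201, and adjusted p = 0.393 with an estimated correlation. That list was not called without PIG-EMPTY replicate 1 or without PIG-LONA replicate 2. Its count of falls was 2 without PIG-EMPTY replicate 1, without PIG-EMPTY replicate 2, without PIG-LONA replicate 2 or with DESeq2, 10 without PIG-LONA replicate 1, 3 without chromosome 6 genes and 1 without the low-count filter. Interferon-stimulated genes were not called (camera adjusted p = 0.0616), although they were called lower with voom (adjusted p = 0.0492) and without PIG-LONA replicate 2 (adjusted p = 0.0407). Of 42 measured, TRIM22 (-0.29 ± 0.05) and OAS2 (-0.54 ± 0.14) fell, and 2 fell adjusted over the list alone. Immediate early genes fell in 5 and rose in 1 of 36 cases (5 and 3 adjusted over the list alone). FOS, DUSP6 (-0.42 ± 0.07), SPRED1 (-0.26 ± 0.04) and PHLDA1 (-0.22 ± 0.05) were among those that fell, and the list was not called (camera adjusted p = 0.165). CCL5, TRIM22, OAS2 and PHLDA1 lost their calls without PIG-EMPTY replicate 2, and SOD2 without either PIG-EMPTY library.

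Genes of G1 and S phase rose by small amounts. Of 42 measured members, 15 rose, 0 fell and 27 did not pass, and 25 rose when adjusted over the list alone. The helicase subunit MCM4 rose from 460 ± 12.6 to 513 ± 5.21 CPM (log2 fold change 0.16 ± 0.03, edgeR adjusted p = 0.00681), the ribonucleotide reductase gene RRM2 was at 0.26 ± 0.04, the chromatin assembly factor gene CHAF1B at 0.29 ± 0.06, and MCM3, the list's single chromosome 6 member, at 0.33 ± 0.04. The median of the list was 0.13. Tested by camera, the list had an adjusted p = 2.76e-15, and adjusted p = 0.308 with an estimated correlation of 0.150. Fry did not call it (adjusted p = 0.0800). Of 45 genes of G2 and M phase, TTK, on chromosome 6, rose (0.19 ± 0.04) and 0 fell. It was also the 1 that rose adjusted over the list alone, with a camera adjusted p = 0.0132, and adjusted p = 0.308 with an estimated correlation. The number of rising G1 and S phase genes was 4 without PIG-EMPTY replicate 1, 2 without PIG-EMPTY replicate 2, 8 with DESeq2, 7 without the low-count filter and 23 with the GC and length trend removed. MCM4 lost its call without either PIG-EMPTY library. TTK lost its call without either PIG-EMPTY library, with DESeq2, without the filter and with the chromosome 6 shift removed, which left 0 rising G2 and M phase genes, against 10 without PIG-LONA replicate 1, 6 without PIG-LONA replicate 2 and 4 with the GC and length trend removed.

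Cell cycle inhibitors and p53 targets included CDKN1A, which encodes p21. It fell from 41.6 ± 0.44 to 30.0 ± 0.13 CPM (log2 fold change -0.47 ± 0.05, edgeR adjusted p = 1.67e-05) although it lies on chromosome 6. The 32 measured p53 targets had 5 falls and 1 rise (8 and 2 adjusted over the list alone). PHLDA3 (-0.35 ± 0.07) and the pro-apoptotic gene BAX (-0.17 ± 0.04) were among the falls. The rise was the polymerase gene POLH (0.26 ± 0.05), on chromosome 6, whose median was 0.17. For these targets camera gave an adjusted p = 0.00256, and adjusted p = 0.308 with an estimated correlation. Of 15 cell cycle inhibitors 3 fell and 1 rose (5 and 1 adjusted over the list alone), CDKN1A, BTG2 (-0.26 ± 0.06) and BTG1 (-0.19 ± 0.05) against CDKN2C (0.18 ± 0.04), and that list was not called (camera adjusted p = 0.223). Falls of p53 targets numbered 3 without PIG-EMPTY replicate 1, 1 without PIG-EMPTY replicate 2, 3 with DESeq2 and 1 without the low-count filter. CDKN1A kept its call under each of these settings, whereas BAX, BTG2 and BTG1 lost theirs without either PIG-EMPTY library, PHLDA3 and CDKN2C theirs without PIG-EMPTY replicate 2, and POLH without PIG-EMPTY replicate 1.

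Genes tied to the NPM1-mutant state were mostly not called. NPM1 stood at 1769 ± 2.60 CPM in PIG-EMPTY and 1791 ± 31.0 CPM in PIG-LONA (log2 fold change 0.02 ± 0.03, edgeR adjusted p = 0.834). HOXA9 (-0.02 ± 0.06) and MEIS1 (-0.03 ± 0.05), which are highly expressed in this leukaemia subtype, and MYC (0.04 ± 0.04) also did not pass. Among 24 HOX cluster and partner genes, PBX2, on chromosome 6, rose (0.18 ± 0.05), as did 1 adjusted over the list alone, and the list was not called (camera adjusted p = 0.562). PBX2 lost its call without either PIG-EMPTY library and with the chromosome 6 shift removed. Of 20 measured stem and progenitor genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone). The receptor tyrosine kinase gene FLT3 rose from 37.2 ± 0.33 to 50.5 ± 1.51 CPM (0.44 ± 0.05, edgeR adjusted p = 2.04e-05), ERG (0.48 ± 0.11) and CDK6 (0.17 ± 0.04) rose, and TAL1 (-0.47 ± 0.07) fell. ERG and CDK6 lost their calls without PIG-EMPTY replicate 1 and with DESeq2. The list was not called (camera adjusted p = 0.841), and its median of -0.06 and mean of -0.05 had the opposite sign to the camera direction. CD34 had counts of 27 and 40 in PIG-EMPTY and 24 and 28 in PIG-LONA, and MPO 83 and 84 against 63 and 107. Neither passed. KIT, with 2, 1, 0 and 0 counts, was too low to be tested.

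Genes of chromosome 6 were higher in PIG-LONA along the whole chromosome. The median log2 fold change of its 799 tested genes was 0.17 (1.12-fold), and 82.2% of them had a positive value, whereas the medians of the other chromosomes ran from -0.02 to 0.01. Chromosome 6 held 5.02% of the tested genes, 48.4% of the higher genes (226) and 14 lower genes. Both PIG-LONA libraries showed the shift, with medians of 0.16 and 0.18 against the PIG-EMPTY mean. PIG-EMPTY replicate 2 lay 0.04 below replicate 1 on this chromosome (median log2 difference -0.04), more than the 0.02 seen at most on any other. The called genes of chromosome 6 included VEGFA, an angiogenic growth factor gene that rose from 54.0 ± 3.36 to 73.8 ± 5.09 CPM (log2 fold change 0.45 ± 0.05, edgeR adjusted p = 2.69e-05). Camera gave the chromosome an adjusted p = 8.14e-28, and adjusted p = 0.513 with an estimated correlation, on 2 residual degrees of freedom. With the shift removed, 17 chromosome 6 genes were higher and 36 lower.

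**Figure D2:**
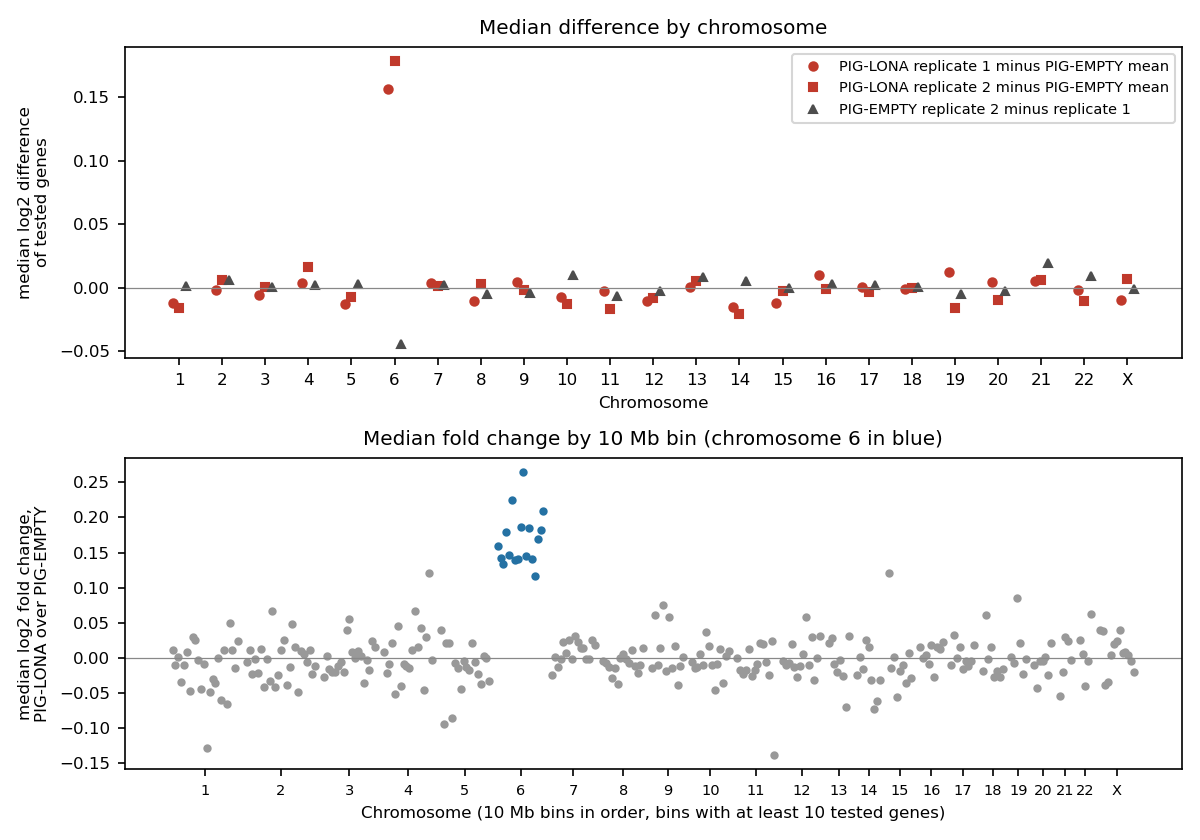
The upper panel plots, for each chromosome, the median log2 difference of its tested genes, with red symbols for each PIG-LONA library minus the PIG-EMPTY mean and grey triangles for PIG-EMPTY replicate 2 minus replicate 1; the lower panel plots the median log2 fold change of each 10 Mb bin in chromosome order. Chromosome 6 lies at 0.16 and 0.18 in the PIG-LONA libraries, and its 17 bins run from 0.12 to 0.26.

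Several lists had most of their rising members on chromosome 6. Nuclear transport genes rose in 4 of 35 cases with 0 falls (4 adjusted over the list alone), and NUP153 (0.25 ± 0.04), XPO5 (0.22 ± 0.04) and KPNA5 (0.32 ± 0.09) lie on chromosome 6 while CSE1L (0.13 ± 0.04) does not. The camera adjusted p was 0.00765, and adjusted p = 0.568 with an estimated correlation. That estimate was 0.273, far above the preset 0.01, so the call at the preset value is doubtful. Abundant long noncoding RNAs rose in 3 of 18 cases (4 adjusted over the list alone), with the snoRNA host genes SNHG32 (0.31 ± 0.06) and SNHG5 (0.17 ± 0.04) on chromosome 6 and SNHG6 (0.17 ± 0.05) elsewhere. Camera gave an adjusted p = 0.0299 at the preset correlation and 0.568 with the estimated one of 0.307, so this call is doubtful too. The list was not called without chromosome 6 genes or with the chromosome 6 shift removed. All 3 rising heat shock genes of 18 measured (3 adjusted over the list alone, where 1 fell) lie there, HSP90AB1 (0.15 ± 0.03) and the near-identical HSPA1A (0.20 ± 0.05) and HSPA1B (0.32 ± 0.06), whose split of reads is uncertain. So do both rising cytosolic ribosomal protein genes of 75 (2 adjusted over the list alone), RPS18 (0.18 ± 0.04) and RPS12 (0.19 ± 0.04). With the chromosome 6 shift removed, NUP153, XPO5, KPNA5, SNHG32, SNHG5 and these 5 heat shock and ribosomal protein genes lost their calls, and the log2 fold change of HSP90AB1 was -0.02. Rising nuclear transport genes numbered 2 without PIG-EMPTY replicate 1, 1 without PIG-EMPTY replicate 2, 13 without PIG-LONA replicate 1, 1 without chromosome 6 genes or with the chromosome 6 shift removed and 2 with library totals, DESeq2 or no low-count filter. The list was not called without PIG-EMPTY replicate 2 or without PIG-LONA replicate 2, nor the noncoding RNAs without PIG-EMPTY replicate 2 or PIG-LONA replicate 1. Rising noncoding RNAs numbered 1 without either PIG-EMPTY library, with DESeq2 or without the low-count filter, 0 without chromosome 6 genes or with the shift removed, 5 with the GC and length trend removed and 6 without PIG-LONA replicate 2.

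MHC class I and its processing had 3 rises and 1 fall among 18 measured members, the same numbers adjusted over the list alone. HLA-E (0.23 ± 0.04), TAPBP (0.19 ± 0.04) and TAP2 (0.17 ± 0.05) rose and PSMB9 (-0.23 ± 0.06) fell, all on chromosome 6. The list was not called (camera adjusted p = 0.789), and its median (-0.00210) and mean (-0.0139) were negative while the camera direction was up. With the chromosome 6 shift removed the list was called lower (median -0.0908, adjusted p = 8.61e-04), HLA-E and TAPBP lost their calls, and TAP2 was at -0.00157. TAP2 also lost its call with DESeq2, with voom and without either PIG-EMPTY library. Replication-dependent histone genes, most of which lack a poly(A) tail and are poorly captured by poly(A) selection, had 14 of 15 measured members on chromosome 6. H2AC6 (-0.54 ± 0.10) and H1-2 (-0.62 ± 0.17) fell and H1-5, with counts of 4 and 3 against 21 and 14, rose, and 2 fell and 1 rose adjusted over the list alone. H1-2 and H1-5 lost their calls without either PIG-EMPTY library. That list was not called (camera adjusted p = 0.310), with a median and mean of 0.03 and a camera direction of down, but it was called lower with the stricter low-count filter (adjusted p = 0.0203) and with the chromosome 6 shift removed (adjusted p = 0.0197).

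The remaining lists fixed for stress, metabolism and RNA quality were not called, with exceptions under other settings given below. Amino acid starvation and unfolded protein response genes had 3 rises and 2 falls among 35 (4 and 2 adjusted over the list alone). STC2 and the serine synthesis gene PHGDH (0.22 ± 0.05) rose, and the cystine transporter gene SLC7A11 (-0.55 ± 0.06) and CEBPB (-0.39 ± 0.08) fell (camera adjusted p = 0.838). The list's median of -0.01 had the opposite sign to its mean of 0.01 and to the camera direction. Hypoxia and glycolysis genes had 1 rise, VEGFA, and 2 falls, HK1 (-0.20 ± 0.04) and ADM (-1.21 ± 0.26), among 33 (2 and 3 adjusted over the list alone; camera adjusted p = 0.526). MYC and ribosome biogenesis genes had 1 rise among 55, also 1 adjusted over the list alone (camera adjusted p = 0.189). It was POLR1C (0.21 ± 0.05), on chromosome 6, whose median was 0.17. Cholesterol synthesis and uptake had 0 changes among 28 genes by edgeR, DESeq2 or voom, with 5 higher and 1 lower at an unadjusted p under 0.05, and a camera adjusted p = 0.0938. INSIG1 was at 0.12 ± 0.04 there. The 15 mitochondrially encoded genes and the 71 nuclear-encoded oxidative phosphorylation genes also had 0 changes by edgeR, DESeq2 or voom. At an unadjusted p under 0.05, 1 mitochondrially encoded gene was higher, and 1 oxidative phosphorylation gene was higher and 2 were lower. In these 3 lists 0 genes passed when adjusted over the list alone. The camera adjusted p of the latter pair was 0.789, as was that of the ribosomal protein genes. The estimated correlations of these latter 3 lists were 0.708 (mitochondrially encoded), 0.533 (oxidative phosphorylation) and 0.878 (ribosomal proteins), far above the preset 0.01. With them camera gave each list an adjusted p = 0.957, and calls at the preset value are doubtful for these lists. The mitochondrially encoded, oxidative phosphorylation and ribosomal protein lists, however, were called lower without PIG-LONA replicate 1 (adjusted p = 1.24e-06, 0.00113 and 2.94e-07) and higher without PIG-LONA replicate 2 (adjusted p = 2.42e-11, 0.00454 and 2.88e-11), in that order. The cholesterol and the MYC and ribosome biogenesis lists were called higher without PIG-LONA replicate 2 (adjusted p = 0.0263 for both), without the low-count filter (0.0109 and 0.0203) and with the GC and length trend removed (0.0463 and 0.0495). PHGDH and POLR1C lost their calls without PIG-EMPTY replicate 2, HK1 without PIG-EMPTY replicate 1, ADM without PIG-LONA replicate 2 and CEBPB with DESeq2.

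Of 12 measured embryonic kidney line genes, which stood for cells of a packaging line, 2 fell and 1 rose (3 and 1 adjusted over the list alone). BEX1 (-0.24 ± 0.04) and SIX2, with counts of 17 and 17 in PIG-EMPTY and 1 and 5 in PIG-LONA, fell and GPC3 (0.35 ± 0.10) rose, with a camera adjusted p = 0.0834 and a fry adjusted p = 0.0484 (lower). GPC3 lost its call without either PIG-EMPTY library. Of 9 dendritic cell genes, the antigen-presenting CD1A (-0.50 ± 0.07) and CD1C (-0.55 ± 0.10) fell and FLT3 rose, with 4 and 3 adjusted over the list alone and a camera adjusted p = 0.411. Erythroid genes, with 3 measured, were too few for a list test. The transferrin receptor gene TFRC (0.22 ± 0.04) and the carbonic anhydrase gene CA2 (0.16 ± 0.04) rose, and both calls were lost without PIG-EMPTY replicate 2. The 2 measured mast cell and basophil genes, GATA2 (0.18 ± 0.16) and MS4A2 (0.12 ± 0.24), did not pass.

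**Figure D3:**
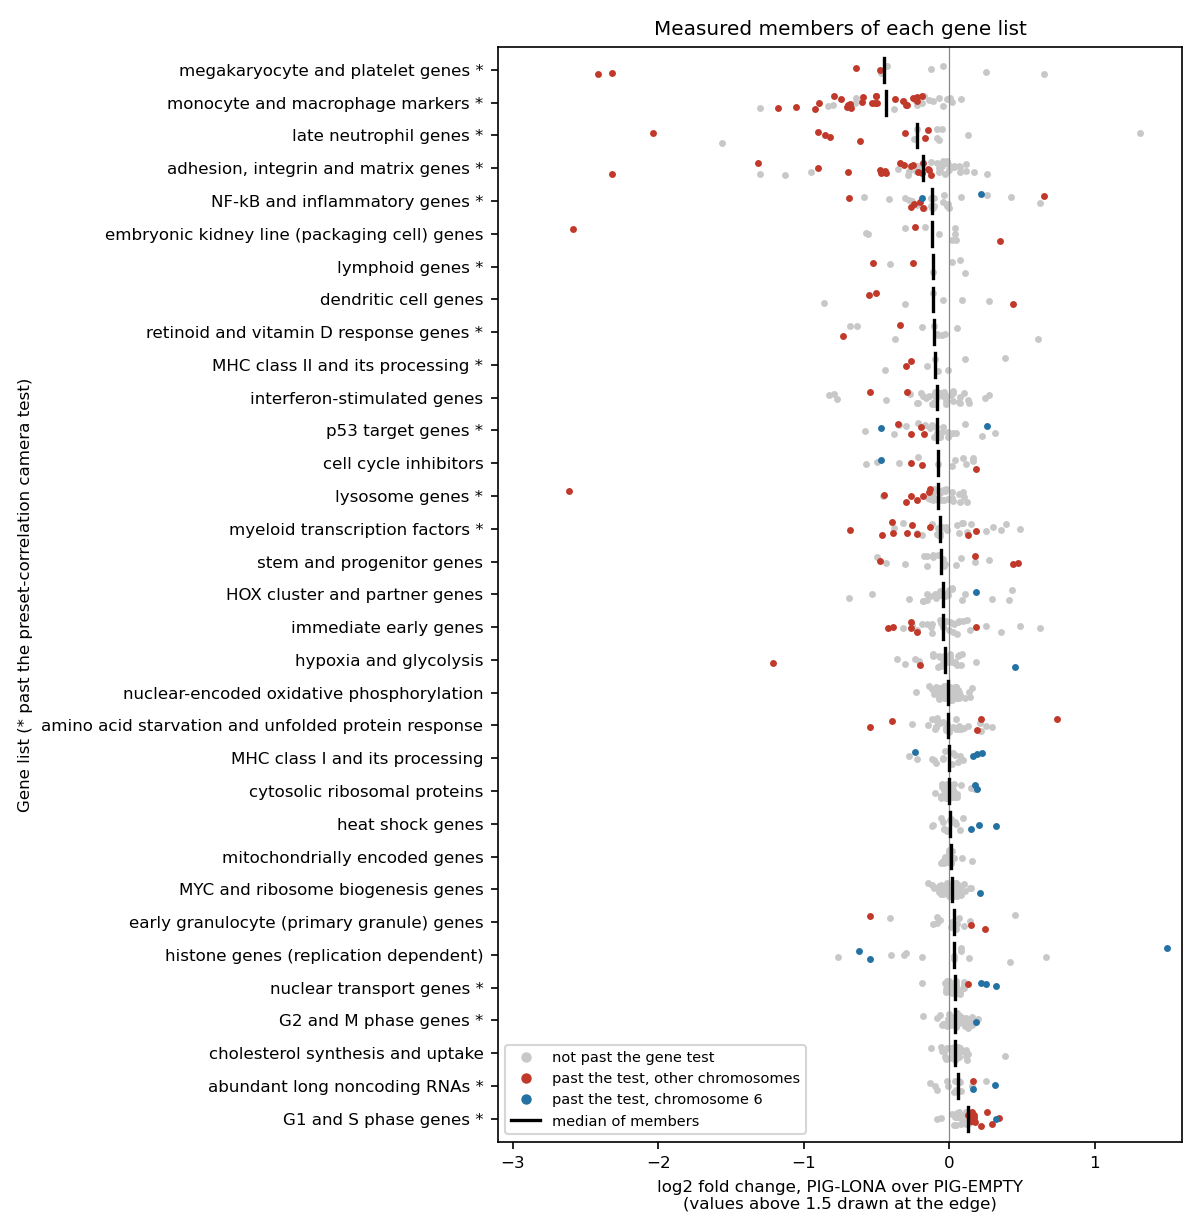
Each point is a measured member of the gene list on its row, placed by its log2 fold change between PIG-LONA and PIG-EMPTY; grey points did not pass the edgeR test, red and blue points did, blue ones on chromosome 6, black bars are medians and asterisks mark lists past camera with the preset correlation. The monocyte and macrophage list lies almost entirely below 0 with a median of -0.44, and the G1 and S phase list lies to the right with a median of 0.13. With an estimated correlation 0 lists passed camera.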

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

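The alternatives without chromosome 6 genes, with the GC and length trend removed and with the chromosome 6 shift removed were chosen after seeing the data. The 1025 calls (467 higher, 558 lower) fell to 473 (219 and 254) with DESeq2, all among the 1025, and to 334 (140 and 194) without a low-count filter, where 29600 genes were tested. They numbered 660 without chromosome 6 genes (219 higher, 441 lower), fewer than the 241 higher and 544 lower that lie elsewhere, and 232 were higher with the chromosome 6 shift removed. All 660 were among the 1025. With the many small p of chromosome 6 left out, the Benjamini-Hochberg cutoff is stricter for the genes that remain. Other causes of the loss elsewhere were not tested. With the GC and length trend removed, 1484 were called, 746 higher and 738 lower, so the totals were nearly equal. Chromosome 6 genes were still tested there, and their median stayed at 0.166. Whether the excess of lower genes on the other chromosomes changed was not counted under this setting. An adjusted p under 0.01 left 528 genes and a 2-fold minimum 68, by construction. Leaving out 1 library gave 466 to 2331 calls, 157 to 1222 higher and 309 to 1109 lower, with the fewest without PIG-EMPTY replicate 2 and the most without PIG-LONA replicate 1. These fits assume that the lone library of a group varies like the others. Their residual spread comes only from the pair that stays whole. The chi-square per gene was 1.81 for the PIG-EMPTY pair and 4.67 for the PIG-LONA pair. A call lost without a PIG-EMPTY library can therefore reflect the wider PIG-LONA pair and not that library. How much of the spread in calls follows from this was not tested. Of the calls shared with the 1025, all kept their direction under each of these settings. The labels do not say whether equal replicate numbers mark a shared day. Deviations of same-numbered libraries had a correlation of 0.0288 across genes, and the replicate block gave 1101 calls and 15 lists, with 1022 of the 1025 genes shared. The other scalings, voom, the legacy test and the stricter filter gave 882 to 1135 calls.

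Of 15 lists called (4 higher, 11 lower), camera with an estimated correlation called 0 (0 higher, 0 lower) and fry 7 (0 higher, 7 lower), 6 of them among the 15. That form of camera rests on 2 residual degrees of freedom here, so it could hardly call a list. Fry's seventh was the embryonic kidney line list. Leaving out 1 library gave 12 to 19 lists, 2 to 9 of them higher, with 2 without PIG-EMPTY replicate 2 and 9 without PIG-LONA replicate 2. The monocyte and macrophage, adhesion and matrix, late neutrophil, megakaryocyte, lysosome, p53 target, retinoid, G1 and S phase and G2 and M phase lists were called by camera at the preset correlation under every setting run. Among 110 named genes called, 42 lost the call without PIG-EMPTY replicate 2, 28 without PIG-EMPTY replicate 1, 10 without PIG-LONA replicate 2, 3 without PIG-LONA replicate 1, 49 without the low-count filter, 22 with DESeq2 (of the 99 it gave an adjusted p) and 21 with the chromosome 6 shift removed. Only 2 of the 110 changed sign under any setting, HSP90AB1 (-0.0165) and TAP2 (-0.00157) with that shift removed. Where 1 library was left out, the pair that set the residual spread also differed. Other causes of the losses were not tested.

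Other changes of sign were in genes and lists not called in the analysis as reported. Of the rule-named genes not called there, 1 passed with the replicate block and 5 with the GC and length trend removed. Over the fits that leave out 1 library, log2 fold changes ran from -0.0862 to 0.0503 for CEBPA, -0.112 to 0.0729 for HOXA9, -0.0578 to 0.00351 for MEIS1, -0.0174 to 0.0895 for MYC, -0.348 to 0.0535 for MPO, -0.373 to 0.580 for MS4A2, -0.0225 to 0.193 for MT-ND4L and -0.00339 to 0.251 for AKR1C3. CEBPA was at 0.00741 with the GC and length trend removed, and ACAT2 (-0.0467) and COX7A2 (-0.0259) turned with the chromosome 6 shift removed. List medians ran from -0.0305 to 0.00745 for hypoxia and glycolysis, -0.0222 to 0.0321 for amino acid starvation, 0.00553 to 0.0867 for early granulocyte genes, -0.101 to 0.103 for mitochondrially encoded genes, -0.0578 to -0.0232 for stem and progenitor genes, -0.0523 to 0.0493 for ribosomal proteins, -0.0604 to 0.0170 for HOX genes and -0.0534 to 0.0431 for oxidative phosphorylation, where the camera direction turned. The mitochondrially encoded, ribosomal protein and oxidative phosphorylation lists were called lower without PIG-LONA replicate 1 and higher without PIG-LONA replicate 2. The direction also turned for ribosomal proteins with voom (median -7.42e-04), for oxidative phosphorylation without the filter (-0.00124) and with the GC trend removed (-0.00202), for stem and progenitor genes without the filter (-0.101) and with the chromosome 6 shift removed (-0.0980), for heat shock genes (-0.00951) and MHC class I (-0.0376) without chromosome 6 genes, and for MHC class I with its shift removed (-0.0908, then called lower). The causes were not tested. For the level of LONA the alternative scaling gave no value, as no row was matched by name. At this depth the simulated test recovered 42.9% of genes changed 1.2-fold against 95.8% of those changed 4-fold.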

Other observations

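The genes of the first 2 paragraphs, the 3 tests on chromosome 6 and the Poisson limit on the liver markers were chosen after the results were seen, as were 3 of the alternatives. Of 5 neighbouring ABC transporter genes on chromosome 17, 2 were lower in PIG-LONA. ABCA8 (68867292 to 68955392, GRCh38) had 27 and 31 counts in the PIG-EMPTY libraries and 2 and 0 in the PIG-LONA libraries (edgeR adjusted p = 7.30e-05), and ABCA6 had 74 and 88 against 16 and 26. Both calls held under every setting that gave a value. ABCA9, between them, had 26 and 34 counts against 18 and 10 and did not pass (edgeR adjusted p = 0.0548), although it passed with upper-quartile scaling, with voom, without PIG-LONA replicate 1 and with the GC trend removed. ABCA10, with 56 and 55 against 29 and 46, did not pass under any setting, and their neighbour ABCA5 was at a log2 fold change of 0.10 ± 0.06 and passed only without PIG-LONA replicate 1.

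Among other genes, SERPINB2 was at -1.02 ± 0.09 and SERPINA1 at -0.71 ± 0.09 (log2 fold change ± SE). The complement receptor gene CR1 fell from 22.9 to 12.5 CPM (-0.87 ± 0.07), and the signalling adaptors TYROBP (-0.69 ± 0.09) and FCER1G (-0.36 ± 0.05), which serve many activating myeloid receptors, fell too. FCGR1A (-0.49 ± 0.06) and FCGR2B (-0.59 ± 0.06) fell, though both have close paralogs that leave their counts uncertain. CSF1R, the receptor of macrophage colony-stimulating factor, was at -0.92 ± 0.15. Among increases off chromosome 6, the chromatin methyltransferase gene EZH2 was at 0.33 ± 0.04 and ASS1, an enzyme of arginine synthesis, at 0.44 ± 0.06. All of these genes kept their calls under every setting run. The amino acid synthesis genes PSAT1 (0.19 ± 0.04) and PYCR1 (0.21 ± 0.05) and the folate enzyme gene ALDH1L2 (0.24 ± 0.05) rose beside PHGDH, but lost their calls without the low-count filter and without 1 or both of the PIG-EMPTY libraries. AKR1C3 (0.13 ± 0.06) passed only without PIG-LONA replicate 1, unlike AKR1C1 and AKR1C2, and the difference between these genes was not tested.

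Chromosome 6 genes were higher in both PIG-LONA libraries. Regulation of the MHC region alone is argued against by the 608 tested genes outside 25 to 34 Mb, whose median was 0.173 while no other chromosome exceeded 0.0126. A GC or length trend is argued against by a median of 0.166 after its removal, against at most 0.0178 elsewhere. All 17 bins of 10 Mb (100%) lay above 0.0465, the 95th percentile of the 277 bins of other chromosomes, so a copy number difference of the whole chromosome in part of the cells may explain the shift. Copy number itself was not measured, the shift of 0.0444 between the PIG-EMPTY libraries was also the largest of any chromosome, and an effect of LONA on the chromosome remains open and untested.

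Monocyte markers were lower and S phase genes higher in PIG-LONA. After removal of the GC and length trend the medians were -0.438 ± 0.0896 and 0.139 ± 0.0141, against -0.437 and 0.1315 before. The nearer of them lay 4.89 SE from 0, which argues against such a trend as the whole cause. This SE came from 1000 resamples of the list members, so it holds no spread between libraries. Carry-over of matrix-producing cells as the source of the FN1 difference is argued against by 3 collagen genes. They summed to 0.464 CPM in PIG-EMPTY, 0.0151 of that difference of 30.7 CPM. FN1 belongs to the adhesion and matrix list, so this test says nothing on the monocyte or S phase genes. Without chromosome 6 genes 2 of the 2 lists were still called by camera in the same direction, but only 2 of 44 monocyte and 1 of 42 S phase members lie there, so the bound set for that test could hardly have been missed, and effects of the chromosome 6 difference on genes elsewhere stay open. An effect of LONA and a difference between the cultures unrelated to it stay open too. Neither list was called with an estimated correlation, a test that rests on 2 residual degrees of freedom.

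Some genes were counted almost only in PIG-EMPTY replicate 1. With at least 20 counts there and at least 10 times the depth-scaled level of any other library, 9 genes were found, against 1 in PIG-EMPTY replicate 2, 1 in PIG-LONA replicate 1 and 0 in PIG-LONA replicate 2. The highest of 100 simulated sets gave 0, which argues against counting noise alone. Those sets were Poisson counts around 1 mean per gene, which could hardly reach the bounds. They lacked the wider spread seen between libraries (chi-square per gene 1.81 for PIG-EMPTY and 4.67 for PIG-LONA), so such spread was not tested. ORM1, a plasma protein gene, had 123, 0, 1 and 1 counts, ZNF521 28, 0, 0 and 0 and MMRN1 32, 0, 0 and 0. RNA of liver cells is argued against by 11 liver markers, which summed to 12 counts there and 18 in PIG-EMPTY replicate 2, with 0 for ALB, although 12 lies barely under the bound of 12.3 set in advance. The exact Poisson 95% upper limit of 21 lies above that bound and below the 123 counts of ORM1. A small clone or subpopulation of cells in that culture remains open and was not tested, and the groups give no explanation for a pattern of 1 library.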
